A study of Canis lupus familiaris with 4 samples.

How the data were processed

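RNA labelled as coming from canine mammary tumours of grade 3 and grade 1 had been hybridised to 4 two-colour Agilent arrays, each holding both grades. Grade 3 carried Cy5 and grade 1 Cy3 on 2 arrays, and the dyes were swapped on the other 2. Spot values had been read with Agilent Feature Extraction 10.7.3.1, per the submitters' processing notes. The deposited median signal and local background columns are intensity values on a linear scale, per the file headers. The deposited processed signals are also intensity values, which Feature Extraction had background-subtracted, detrended and dye-normalized with linear and lowess steps, per the file headers. The deposited LogRatio column holds the log10 of Cy5 over Cy3 processed signal, per the file headers. The deposited value table of the series holds log10 ratios that differed from that column by at most 4.99e-06 once the sign of the swapped arrays was turned, so it runs as grade 3 over grade 1 on all 4 arrays, and each of its columns had a median of 0. The direction of every ratio was taken from the dyes in the labels.

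Values were computed in R 4.3.3 with limma 3.58.1. Mean signals had been planned, but the files used here have no such column, and median signals took their place. Background was corrected with normexp and an offset of 50, fitted on all spots, and each array was normalized with loess, control spots having weight 0. One step departs from the plan written before the data were examined. Feature Extraction marked the local background of some spots as an outlier, and these reached 309565 intensity units where the median background of the array and channel was 41. With them the normexp noise SD was 3313 units in the Cy5 channel of replicate 2 with grade 3 in Cy5, and the fit failed to describe that channel. Local backgrounds with such a mark were therefore replaced by the median of their array and channel, after which that SD was 0.18. Between 151 and 2352 backgrounds per array and channel were replaced, while only 0 to 28 were over 5 times the median. This replacement was chosen after the planned correction had been run and its counts of calls, and those of other settings, had been seen. Both sets of counts are reported.

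Between 11 and 39 spots per array with a non-uniformity or population outlier mark in either channel were left out, and spots of one probe were averaged. No spot was saturated. Of 43603 probes, 35412 were well above background on all 4 arrays in at least one grade and were tested. Depth on arrays is signal over background. The median Cy5 signal lay between 289 and 402 units on a median background of 39 to 41, and the median Cy3 signal between 215 and 354.5 units on 28 to 32. Between 80.6% and 84.5% of probes per array and channel were well above background. The number of arrays limits the precision.

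The fit had a grade term and a constant probe-specific dye term, moderated with eBayes (2 residual and 7.49 prior degrees of freedom), two-sided, with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05. Errors of fold changes are the moderated SE over 4 arrays. Levels are single-channel log2 intensities after loess and Aquantile, with the SD over 4 arrays. A gene not well above background on any array in one grade has only a bound. It is the bright grade's mean against the dim grade's mean of, per array, the higher of the probe's own signal and the lowest signal among probes well above background.

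Probes were named through their RefSeq accession, without version, in a table of the assembly UU_Cfam_GSD_1.0. Of 43603 probes, 1648 (3.78%) matched a symbol, among them 1644 of the 1740 with an NM accession. The 19498 probes with an Ensembl transcript and 22365 with other accessions are unnamed here, and no coordinates were used. The named probes tested numbered 1431, for 925 genes. The brightest probe stood for its gene. Of 347 genes with several tested probes, 14 had probes called in opposite directions, TCAP and DMD among them.

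The genes named in the text follow a rule fixed beforehand. It takes the 10 highest and 10 lowest called genes with one sign on all 4 arrays and both grades above background, up to 5 genes per direction with a bound only, the 3 smallest p and the brightest member of each gene list, and 10 genes of tumour biology. Some genes that the rule takes are not reported here, and counts include them. Lists numbered 24, and the 14 with at least 5 measured members were tested with camera at a preset correlation of 0.01 among 924 named genes with values on all arrays. The probe test was checked on simulated data for the comparison of grades over 35412 probes: it recovered 30 of 50 probes changed 1.25-fold and 50 of 50 at each of 1.5-fold, 2-fold and 4-fold, with 7 unchanged probes called. Far fewer probes were changed there than the 21833 called in the data, and the simulated errors were independent between arrays. The 7 therefore do not estimate the number of false calls in the data. In 20 simulated sets of 14 lists of 7 among 924 genes, the list test called a list shifted by 0.5 on the log2 scale in 14 sets and 1 of 260 unshifted lists. The simulated genes varied independently of each other, so this check does not cover lists whose members are correlated.

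The alternatives fixed beforehand were no background subtraction, the processed signals, the series value table, median centring, scaling between arrays, 2 filters on dim probes, outlier spots kept, no dye term, the replicate number as a block, eBayes with trend and robust settings, other thresholds, other list tests, the mean of a gene's probes, and leaving out each array. Chosen after seeing the data were the replacement of marked backgrounds, scaling to spike-in control probes, the replicate number as a fixed term, and list tests against all probes. The normexp fit with marked backgrounds as measured is the planned correction and is given as an alternative. The spike-ins are 10 E1A control sequences with 32 spots each.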

Results

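The series compared gene expression in canine mammary tumours of the highest malignancy (grade 3) with that in less malignant tumours (grade 1). Each of the 4 arrays held RNA of both grades, with grade 3 in Cy5 on 2 arrays and in Cy3 on the other 2. The labels call the arrays biological replicates, numbered as parts of 4 on 3 arrays and of 3 on 1 array, and do not say which arrays share an RNA extract. All 4 lay on 1 slide, and p-values measure only the spread between these arrays, which may be technical. The titles name tumours, while the protocols in the labels describe cancer cells cultured with monocytes for at least 72 h and then sorted, so the kind of sample is not settled. Only 1648 of 43603 probes could be given a gene name, and 925 named genes were tested.

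Among named genes with signal in both grades, the highest in grade 3 were MYH2, MYH1, H19, CSN2 and COL2A1, and the lowest were CXCL8, CNGA1, SLC15A1 and MMP3. MYH2, a fast skeletal muscle myosin heavy chain, was 23.4-fold higher (log2 fold change 4.55 ± 0.05 SE, n = 4 arrays, limma adjusted p = 1.52e-11), by its brightest probe, and 5.99-fold by the mean of its probes. CXCL8, a chemokine that attracts neutrophils, was 31.0-fold lower (log2 fold change -4.95 ± 0.06 SE, n = 4, limma adjusted p = 3.96e-11). Of 35412 tested probes, 11031 were higher and 10802 lower in grade 3 at an adjusted p under 0.05, and 507 and 621 of these changed at least 2-fold. Among named genes 223 were higher, 426 lower and 276 not called. The median size of a log2 fold change was 0.19 and the median SE 0.05. Of the called probes, 18322 had one sign on all 4 arrays and 3511 did not.

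Those counts depended on the processing. With the background correction as written before the data were examined, 2327 probes were higher and 4411 lower; the replacement of outlying local backgrounds used for the counts above was chosen after these had been seen. The planned correction ended the calls of 29 named genes: the 8 with a bound only, IL1B and POU1F1 among them, and MYH7, KLK5, MMP3, IL6, CCL7, KLRD1, CTLA4, CD28, MS4A1, BRCA1, OXTR, CAV1, SNAI2, CD44, CA9, LEP, RHAG, GYPC, MYC, HSPB1 and RPS18. It moved 15 folds of named genes toward 1 by over 1.5 times, among them those of MYH2, MYH1, MYH7 and OPTC to 12.6, 5.74, 2.08 and 2.79 higher and of MMP3, ADGRE3, CCL7, IL6, MS4A1 and KLRD1 to 2.83, 2.96, 2.20, 1.93, 1.88 and 1.75 lower. The bounds given further on hold only for the correction used here. The processed signals moved 14 away from 1, those of all genes with a bound only, OPTC (10.0-fold higher), CNGA1, IL6, MS4A1 and KLRD1 (15.5-fold, 4.99-fold, 5.00-fold and 4.66-fold lower) and MMP3 (log2 fold change -3.42). Median centring in place of loess gave 15630 higher and 8835 lower, so that 63.9% of calls were higher in place of 50.5%, and ended the calls of VWF, CD44, ADM, PPARG, LEP, MYC, RHAG and GYPC. Without a dye term the calls of CAV1, COL1A2, CA9, LEP, RHAG, GYPC, MYC, HSPB1, RPL23 and RPS18 were lost. Spike-in controls were lower in grade 3 by a mean log2 of -0.67, and scaling to them moved the median of all probes from 0.0046 to 0.67, with 32970 probes higher and 1149 lower and 26 of 92 named genes on the other side of 0. That scaling moved the medians of the 5 lists of inflammation, MHC class II, interferon, macrophage and T cell genes to between -0.184 and 0.325. All changes below are relative to the probes of the same array.

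**Figure D1:**
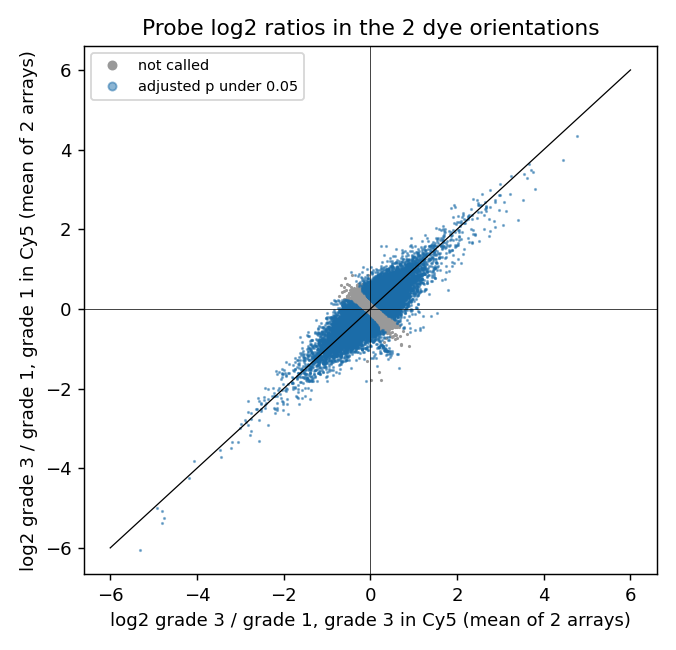
Each point is 1 of the 35412 tested probes, with its mean log2 ratio of grade 3 over grade 1 on the 2 arrays with grade 3 in Cy5 (x axis) and on the 2 with grade 1 in Cy5 (y axis). Blue probes passed an adjusted p of 0.05, and the diagonal marks equal ratios; the correlation across probes, which are not independent replicates, was 0.797.

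Myosin heavy chain genes led the muscle list. Of the 6 measured members of the skeletal and smooth muscle list, 5 were higher and 1 lower, with a median log2 fold change of 1.52 (camera adjusted p = 0.000992; adjusted p = 0.276 with an estimated correlation). MYH1 was 10.6-fold higher (log2 fold change 3.40 ± 0.05) and MYH7, the slow and cardiac heavy chain, 3.44-fold (1.78 ± 0.05). MYH8, a perinatal heavy chain outside the list, was 5.12-fold higher (2.91-fold with the planned background correction), and CA3, a carbonic anhydrase abundant in muscle, 4.32-fold. These heavy chains are paralogs of similar sequence, and probes can detect more than one of them. TCAP, a sarcomere protein, was 2.40-fold higher by its brightest probe, but its other 3 probes had log2 fold changes of -0.22, -0.18 and -0.12, of which the first pair were called lower. DES, the muscle intermediate filament protein, fell by 0.14 on the log2 scale. With the mean of a gene's probes MYH1 was 5.12-fold and MYH7 2.15-fold higher and the list median was 0.642, and with the planned background correction 1.03. In a second muscle list, written after the first results, 4 of 11 measured genes were higher, 5 lower and 2 not called, with a median of -0.028.

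Both measured milk genes rose. CSN2, encoding beta-casein, was 7.03-fold higher (log2 fold change 2.81 ± 0.06), and LALBA, the alpha-lactalbumin gene, 5.66-fold (2.50 ± 0.05). H19, an imprinted noncoding RNA, was 8.34-fold higher, OPTC, encoding opticin, 5.65-fold (2.50-fold by the mean of its probes), and TMEM132C 4.51-fold. In the cartilage and bone list, 2 of 5 members rose and 3 fell. COL2A1, the main cartilage collagen, was 6.96-fold higher and ACAN, encoding aggrecan, 3.21-fold (1.80-fold by the mean of its probes). ALPL, a bone and liver phosphatase, was 3.08-fold lower, and SOX9 and COL9A2 fell by 0.36 and 0.30 on the log2 scale. The list was not called (camera adjusted p = 0.597), and its median of -0.30 opposed its mean of 0.44 and the direction of the test.

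Keratinocyte genes rose by less. Of 7 measured members of the skin keratinocyte list, 6 were higher, with a median log2 fold change of 0.42 (camera adjusted p = 0.00283; adjusted p = 0.276 with an estimated correlation). DSG1, a desmosomal cadherin, was 1.85-fold higher, KRT1 1.80-fold and KLK5, a skin protease, 1.65-fold. The list's call was lost with spike-in scaling (adjusted p = 0.136, median 1.09), and with median centring its median was 0.66.

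**Figure D2:**
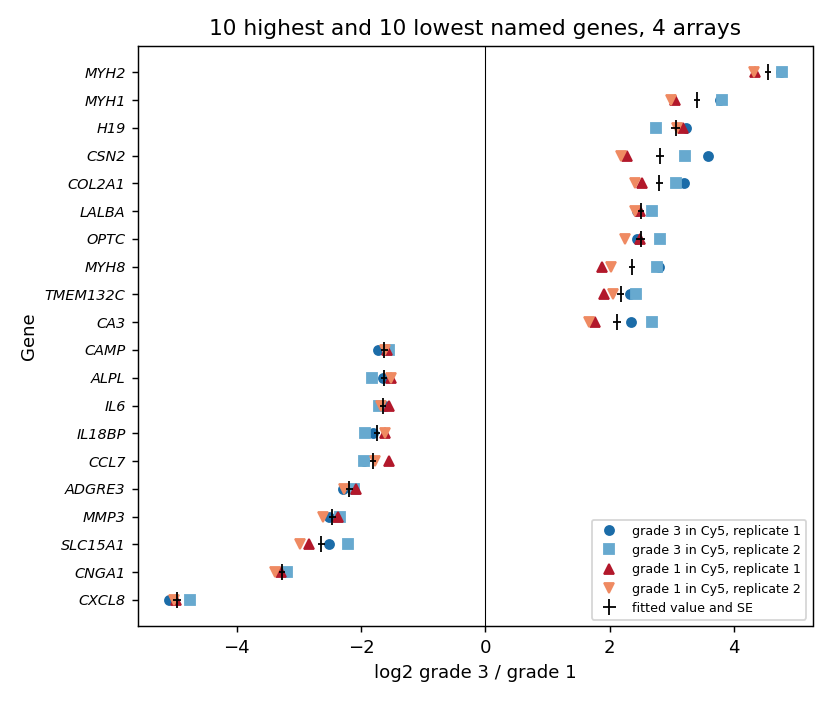
Log2 ratio of grade 3 over grade 1 (x axis) of the 10 highest and 10 lowest named genes on each of the 4 arrays, with the fitted value and its SE as black crosses. All 4 arrays lie on one side of 0 for each gene, as the rule that picked these genes required. The fitted values run from -4.95 for CXCL8 to 4.55 for MYH2.

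Inflammatory genes fell. In the inflammation and neutrophil list 14 of 18 measured members were lower, 1 (SELE, an endothelial adhesion molecule) was higher and 3 were not called. The median log2 fold change was -0.69 (camera adjusted p = 0.00613; adjusted p = 0.276 with an estimated correlation). IL6 was 3.11-fold lower, S100A8, a calcium-binding protein of neutrophils, 2.94-fold, and PTGS2, the inducible cyclooxygenase, fell by 1.30 on the log2 scale. IL1B was not well above background on any array in grade 3 and was at least 4.32-fold lower, though 2.28-fold and not called with the planned background correction. Outside the list, the lowest genes included the chemokine CCL7 (3.50-fold lower), the interleukin 18 inhibitor IL18BP (3.35-fold), the antimicrobial peptide gene CAMP (3.08-fold) and the leukocyte receptor gene ADGRE3 (4.55-fold).

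Antigen presentation and interferon genes fell as groups. All 6 measured MHC class II genes were lower, with a median log2 fold change of -0.85 (camera adjusted p = 0.00613; adjusted p = 0.276 with an estimated correlation). The gene listed as HLA-DRB1 was 2.12-fold lower, DLA-DOB 1.99-fold and DLA-DQB1 1.97-fold, and these polymorphic paralogs can share probe signal. Of 8 interferon response genes 7 were lower and 1 not called, with a median of -0.68 (camera adjusted p = 0.00613; adjusted p = 0.276 with an estimated correlation). OAS2 was 2.69-fold lower, MX1 2.38-fold and the immunoproteasome subunit PSMB9 1.92-fold.

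Macrophage and T cell markers were also lower. Of 13 macrophage and monocyte genes 11 fell, TLR2 rose by 0.36 on the log2 scale and 1 was not called, with a median of -0.80 (camera adjusted p = 0.00613; adjusted p = 0.276 with an estimated correlation). The Fc receptor gene FCGR1A was 2.59-fold lower, the scavenger receptor gene CD163 2.20-fold and the monocyte chemokine gene CCL2 2.06-fold. Of 10 T and NK cell genes 9 fell, with a median of -0.34 (camera adjusted p = 0.0401; adjusted p = 0.276 with an estimated correlation). KLRD1, an NK cell receptor gene, was 2.65-fold lower, CTLA4 1.70-fold and CD28 1.39-fold. The T and NK cell call was lost on leaving out replicate 1 with grade 1 in Cy5 (adjusted p = 0.0844) or replicate 2 with grade 3 in Cy5 (0.0558), and with same-numbered arrays averaged (0.135). It was also lost with both channels above background (0.0716), with the planned background correction (0.277, median -0.18) and with spike-in scaling (0.357, median 0.325). With the processed signals or the series value table the median was -0.932. The B cell gene MS4A1 was 2.92-fold lower and CD38 1.39-fold, too few genes to test.

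**Figure D3:**
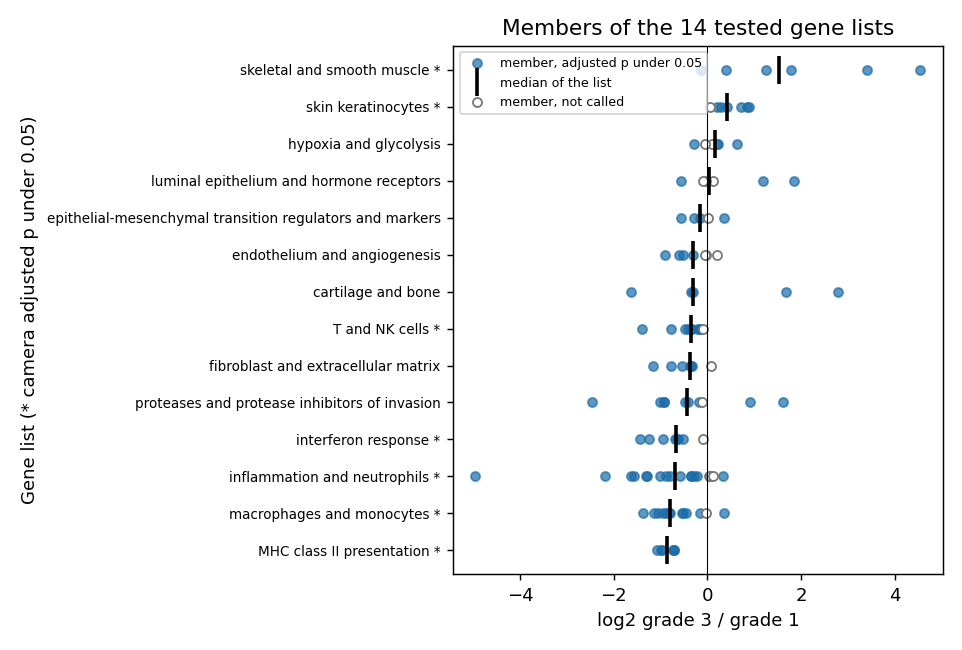
Log2 fold change of grade 3 over grade 1 (x axis) of each measured member of the 14 tested gene lists. Filled points passed an adjusted p of 0.05 over all probes, open points did not, black bars mark list medians, from -0.85 for MHC class II to 1.52 for muscle, and asterisks mark lists called by camera.

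Matrix and vascular genes were mostly lower, without a call on their lists. Of 7 fibroblast and matrix genes 6 fell (camera adjusted p = 0.113), among them COL1A1 (2.24-fold lower), TNC (1.72-fold) and COL1A2, whose log2 fold change of -0.54 ± 0.06 had opposite signs in the dye orientations. Of 10 genes of invasion proteases and their inhibitors, 7 fell and 2 rose (camera adjusted p = 0.24). The matrix protease gene MMP3 was 5.51-fold lower, the inhibitor gene TIMP1 2.01-fold and the cathepsin gene CTSS 1.90-fold. Of 7 endothelial genes 4 fell and 3 were not called (camera adjusted p = 0.27), with ANGPT2 1.88-fold, KDR 1.53-fold, EDNRB 1.44-fold and VWF 1.23-fold lower. Of 5 genes of epithelial-mesenchymal transition 3 fell, S100A4 and CD44 by 0.56 and 0.28 on the log2 scale, and SNAI2 rose by 0.35 (camera adjusted p = 0.857). The calls of CD44 and SNAI2 were lost with the planned background correction (adjusted p = 0.0585 and 0.146).

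Epithelial genes went both ways. Of 6 luminal genes 2 rose, TFF3, a secreted trefoil peptide gene, by 3.62-fold and MUC1, a mucin gene, by 2.27-fold, and the progesterone receptor gene PGR was 1.49-fold lower (camera adjusted p = 0.211). ERBB2 had a log2 fold change of -0.03 ± 0.05 (adjusted p = 0.666) and CLDN3 0.11 ± 0.05 (adjusted p = 0.0814), neither of them called, though with median centring both were called higher (0.21 and 0.36). The myoepithelial genes OXTR and CAV1 had log2 fold changes of 0.29 and 0.25, and both calls were lost with the planned background correction (adjusted p = 0.127 and 0.0506). ESR1, MKI67, CDH1 and VIM were not analysed here. Of 6 hypoxia and glycolysis genes 3 rose and ADM fell (camera adjusted p = 0.211). GAPDH was 1.55-fold higher, CA9 1.18-fold and ADM 1.21-fold lower. CA9 was above 0 on 3 of 4 arrays, and its call was lost with the planned background correction (adjusted p = 0.317) and without a dye term (0.0981).

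Lists under 5 measured genes were not tested. Of 40 listed mitosis genes only 2 were measured, and both fell, BIRC5 by 1.82-fold and ASPM by 1.38-fold. Of 39 listed genes of DNA replication and repair 3 were measured. The repair gene BRCA1 was 1.20-fold lower, while BRCA2 had a log2 fold change of -0.11 ± 0.05 (adjusted p = 0.0933). With spike-in scaling ASPM, BRCA1 and BRCA2 turned to 0.21, 0.41 and 0.56, and BIRC5 had -0.19. The adipocyte genes ADIPOQ, PPARG and LEP were 2.68-fold, 1.22-fold and 1.17-fold lower, and CD36 had 0.08 ± 0.05 (adjusted p = 0.16). LEP had opposite signs in the dye orientations, and its call was lost on leaving out replicate 2 with grade 3 in Cy5 (adjusted p = 0.0516). The red cell genes RHAG and GYPC fell by 0.31 and 0.18 on the log2 scale, RHAG with opposite signs in the dye orientations, and CA1 had 0.05. The RHAG probe had a log2 level of 17.5 in grade 3, against 9.01 for GYPC and 9.03 for CA1, and its target was not checked. CD36 and CA1 were called higher with median centring (0.32 and 0.20). Of the stress genes NR4A1 and HSPB1 rose by 0.59 and 0.25, HSPB1 with opposite signs in the dye orientations, and MYC fell by 0.36. The ribosomal genes RPL23 and RPS18 rose by 0.23 and 0.14, RPS18 with opposite signs in the dye orientations, and RPL27 had -0.07 ± 0.07 (adjusted p = 0.394). With the processed signals the calls of GYPC, HSPB1 and RPS18 were lost, as were those of GYPC and RPS18 on leaving out replicate 1 with grade 3 in Cy5 or replicate 2 with grade 1 in Cy5. The replicate number as a fixed term also ended the call of RPS18 (adjusted p = 0.052). None of the listed oxidative phosphorylation genes was among the named probes. Adjusted over the list alone, the counts of the 24 lists were the same, except that ANGPT1 was also called higher in the endothelial list.

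Genes with signal in 1 grade only had bounds. POU1F1, a pituitary transcription factor gene, was at least 7.23-fold higher in grade 3 by one probe, 3.00-fold and not called with the planned background correction, and its second probe had a log2 fold change of -0.04. SST, encoding somatostatin, had a bound of 1.49-fold higher and HSD3B2, a steroid dehydrogenase gene, of 1.31-fold higher. The bounds of TSHR, SLBP2, CYP19A1 and IAPP were 1.39-fold, 1.27-fold, 1.18-fold and 1.16-fold lower. For SST and SLBP2 the bound equalled the fitted fold, so it leaves no margin for error. With the planned background correction SST was 1.22-fold higher and SLBP2 1.10-fold lower, and with the processed signals 10.0-fold and 4.28-fold. No gene with a bound only was called with the planned correction. Other genes far lower in grade 3 were CNGA1, a channel subunit gene (9.63-fold), and SLC15A1, a peptide transporter gene (6.21-fold), and with the planned background correction 4.65-fold and 3.63-fold. Of the 50 highest probes 12 were named and of the 50 lowest 8. The highest unnamed probes, TC73419 and ENSCAFT00000004474, had log2 fold changes of 4.09 and 3.59, and the lowest, DN391919 and ENSCAFT00000015179, -4.94 and -4.21.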

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

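In 106 results, 92 named genes and 14 list means, the 4 arrays were searched for one far from the others, and 3 genes passed Dixon's critical value for 4 values. For 4 independent normal values chance marks about 1 in 20. Here a dye effect widens the range of the 4 values, which lowers that share, and list means reuse named genes. Whether 3 is more than chance gives is therefore not known. For BRCA1 replicate 2 with grade 1 in Cy5 had a log2 ratio of -0.06 against -0.35, -0.31 and -0.33 on the others (gap over range 0.863). For TFF3 replicate 2 with grade 3 in Cy5 had 1.45 against 1.97, 1.97 and 2.03 (gap over range 0.89). For CTLA4 the same array had -0.57 against -0.84, -0.84 and -0.82 (gap over range 0.907).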

How the results depend on the processing

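Spike-in scaling, the fixed replicate term and the list test against all probes were chosen after seeing the data. The normexp fit with marked backgrounds as measured is the correction as planned, and the replacement reported in its place was chosen after its counts were seen. Causes were not tested unless the construction of a setting shows them. The counts of 11031 higher and 10802 lower probes stayed within 1.5 times, between 7949 and 15630 higher and between 7777 and 11271 lower, under all alternatives except the 3 named next. Leaving out 1 array gave 9077 to 10975 higher and 8990 to 10800 lower. A fold of at least 2 left 507 and 621 by construction. The normexp fit as planned gave 2327 and 4411, with 6726 probes called in the same direction in both fits, and spike-in scaling gave 32970 and 1149.

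The differences between replicates 1 and 2 in the 2 dye orientations had a correlation of -0.0909 over probes. This shows no pairing by replicate number, but it cannot exclude that arrays share an extract. Averaging same-numbered arrays as a replicate block gave 11623 higher and 11271 lower, the number as a fixed term 10925 and 10641, and duplicateCorrelation was not run, since limma gives no estimate with 2 terms on 4 arrays. The T and NK cell list lost its call under the averaged block (adjusted p = 0.135), with both channels above background (0.0716), with the planned normexp fit (0.277), with spike-in scaling (0.357), and on leaving out either of 2 arrays (0.0558 and 0.0844), but not the other 2 (0.0359 and 0.0387). With an estimated correlation all 7 called lists had 0.276. Fry, which compares a list with no other genes, called the luminal (0.0317), fibroblast (0.0065), epithelial-mesenchymal (0.00968), protease (0.0065), endothelial (0.0155) and cartilage (0.00327) lists too. Against all probes the fibroblast (0.00758), protease (0.0259) and endothelial (0.0469) lists were called and the cartilage list turned (0.996). The epithelial-mesenchymal list turned with the mean of a gene's probes (0.969) and with spike-in scaling (0.702), as did the cartilage list (0.769); with that scaling the protease list was called (0.0327) and the keratinocyte list was not (0.136).

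Median centring turned BRCA2 to 0.10, LEP to 4.45e-05, RPL27 to 0.14 and ERBB2 to 0.21, and the planned normexp fit turned CD36 to -0.012. Spike-in scaling, which adds one value to all probes, turned 26 of 92 named genes, among them TSHR (0.12), SLBP2 (0.33), CYP19A1 (0.43), IAPP (0.39), ASPM (0.21), BRCA1 (0.41), BRCA2 (0.56), PGR (0.096), COL1A2 (0.12), S100A4 (0.11), CD44 (0.39), KDR (0.055), EDNRB (0.14), VWF (0.37), CD28 (0.20), CD38 (0.19), ADM (0.39), PPARG (0.38), LEP (0.45), RHAG (0.36), GYPC (0.49), MYC (0.31), RPL27 (0.60) and ERBB2 (0.64). The planned normexp fit ended 29 of the named genes' calls, median centring 8, spike-in scaling 6 (PGR, TNC, COL1A2, S100A4, KDR and CTLA4) and no dye term 10. On leaving out 1 array RPL27 ranged from -0.19 to 0.043 and ERBB2 from -0.052 to 0.0013, and neither was called in the fit of all 4. Leaving out 1 array ended the calls of GYPC, RPS18, LEP and CYP19A1, and RPL27, CLDN3 and BRCA2 became called. Signal over background limits the dimmest genes, such as those with bounds only.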

Other observations

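The tests of dye bias, of scaling and of the kind of sample were chosen after the results they bear on had been seen. The 2 further gene lists were written before their values were computed.

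Leukocyte genes outside the tested lists were also mostly lower in grade 3. Of 18 measured genes in a second leukocyte list, 16 were lower, 1 (IL2RG, a cytokine receptor chain gene) was higher by 0.63 on the log2 scale and 1 was not called. The iron transporter gene SLC11A1 fell by 1.21 on the log2 scale, the costimulatory receptor gene CD40 by 1.02, the mast cell receptor gene FCER1A by 0.99 and the lymphocyte surface gene CD52 by 0.70.

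Skeletal muscle genes higher in grade 3 were first set against muscle tissue in the samples. A second list of muscle genes had 11 measured members, with a median log2 fold change of -0.028 and an upper quartile of 0.193, below the 0.5 that muscle tissue was set to give. CKMT2 rose by 0.58, and the muscle genes MYOZ1 and CLCN1 fell by 0.27 and 0.30, which argues against muscle tissue as the whole source, though the list holds cardiac genes such as TNNT2 and PLN. Outside the myosin heavy chain family, 1 of 14 measured muscle genes of both lists, TCAP, was at least 2-fold higher, and only by one probe. Cross-hybridisation among the heavy chain probes may therefore add to the pattern, and this explanation stays open. CA3, from no heavy chain gene and in neither list, was higher by all 3 of its probes (log2 fold changes 2.11, 1.39 and 1.23). CA3 was picked for being among the highest named genes in these same data, so its rise does not count against cross-hybridisation. Whether the difference comes from the grade of the tumour cells was not tested.

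A smaller share of leukocytes in the grade 3 samples is a candidate explanation of the lower leukocyte lists. The second leukocyte list had a median log2 fold change of -0.375, against -0.0927 for all named genes, which narrowly missed the gap of 0.3 fixed beforehand, so the test left this open. A constant dye bias of a probe is taken up by the dye term, which the dye swap keeps apart from grade. Of the members called lower in the 5 lists, 47 of 47 were below 0 in both dye orientations. They were picked by that same fit, so their signs add little to this. With spike-in scaling the MHC class II and macrophage medians were -0.184 and -0.13, those of inflammation and interferon genes -0.0212 and -0.00743, nearer to 0 than the spike-in SD of 0.063, and that of T and NK cells 0.325, so whether these transcripts fell in absolute amount cannot be told apart from a difference in RNA content or spike-in amount. Lower transcript levels per cell in grade 3 were not tested.

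RNA of tumour tissue holding many cell types, rather than of sorted cultured cells, is a hypothesis on the conflict between titles and protocols. For 8 of 8 cell types other than macrophages and epithelium, over 0.5 of the measured markers were well above background in both grades on all 4 arrays, including 7 of 7 fibroblast, 7 of 7 endothelial, 4 of 4 adipocyte and 7 of 10 T and NK cell genes. Of all 1045 named genes on the array 896 passed as well, so almost any list would have done so, and tissue and cultured cells cannot be told apart by this test. No RNA of sorted cells was compared here.

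The 10 spike-in sequences had log2 ratios of grade 3 over grade 1 between -0.794 and -0.602 after loess, with an SD of 0.063 over sequences, and a mean of -0.446 after median centring. The dye term passed the threshold for 7048 probes.

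The 4 arrays can be split into 2 and 2 in 3 ways, too few to give a share under 0.05. The grouping by the labels, 1 of the 3, called 21833 probes, and the highest of the other splits called 0. In the other splits the difference between grades adds to the residual spread, which lowers their calls, so this comparison says nothing about chance.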
